A study of Homo sapiens with 6 samples.

How the data were processed

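The study measured RNA of HaCaT cells, a spontaneously immortalized human keratinocyte line, after transfection with siRNAs against PAXBP1 or with control siRNA. There were 6 libraries, 3 per group, assigned from the genotype each sample was labelled with. The labels describe total RNA extracted with TRIzol and Illumina libraries, and name neither the selection of poly(A) RNA nor the strand protocol. The siRNA sequences and the time between transfection and harvest are not given in the sources used here. Nothing in the labels says whether the 3 samples of a group came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

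Read counts per gene were deposited for 58735 genes of build hg38, with gene IDs, coordinates, lengths and biotypes in the same table. Per the submitters' processing notes, the tools were HISAT2 2.0.5 and featureCounts 1.5.0-p3. The strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited counts were whole numbers that summed to between 16254032 and 20311280 per library. The authors also deposited FPKM values of the same genes. In each library the FPKM equals the count divided by the gene length in the table and by 1 library total, which differed from the summed counts by between -2.06% and 0.23%. Every row of the table was a gene, and every per-sample column was used. Gene IDs were also found in GENCODE release 29, which supplied 3' UTR and coding sequences for the closing section.

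Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a count minimum of 10 in at least 3 samples, which left 15277 genes. Libraries were scaled by TMM. The quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) compared knockdown with control without covariates, since the labels name no batch, day or shared number. It is two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are TMM-scaled CPM values (counts scaled by library size), as mean ± SD over the 3 libraries of a group. Fold changes are knockdown over control, and the SE of a log2 fold change was taken from the fold change and its F statistic. At these totals a gene at 1 CPM had between 16 and 20 reads per library, so folds of genes near that level are imprecise.

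The 30 gene lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated from the data, and fry tested whether the members moved on balance in 1 direction. The repeat raised the adjusted p also in lists whose estimated correlation was at or below 0.01. A call lost in the repeat therefore does not by itself show that the members were correlated. The genes to be named were also set by rule before the data were examined. The rule took PAXBP1, PAXBP1-AS1, SYNJ1, GCFC2, TFIP11 and DHX15. It took the 10 highest and 10 lowest fold changes among protein-coding genes with a call, an average log2 CPM of at least 1 and no overlap between groups. It took the 5 smallest p-values per direction, up to 4 members of each list by p, and 3 non-coding genes per direction. Other members are named to describe a list and were chosen after their values were seen. The single-gene results of some list members are not reported here.

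The alternatives were DESeq2 size factors or upper-quartile scaling in edgeR, no low-count filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), protein-coding genes only, and leaving out each library in turn. A further alternative, without genes that hold certain sequence words, was chosen after seeing the data.

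The test was checked on counts simulated from the means, dispersions and library sizes of these samples. The count filter kept 14980 of the simulated genes. Before that filter, 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. Of these, in that order, 70.1%, 82.1% and 95.5% were recovered, and 17 unchanged genes were called, 9.3% of the calls. That share is above the threshold set for the adjusted p. Few genes were changed in the simulation, while 62.5% of the tested genes were called in the real data. Recovery, false calls and TMM scaling under such widespread change were therefore not tested. In a simulated list test, a list of 30 genes shifted by 0.5 on the log2 scale was called up and 0 of 20 unshifted lists were called. Genes were simulated independently there, while estimated correlations of the real lists reached 0.508, in the mitochondrially encoded list. This check therefore does not cover false calls of correlated lists.

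For the closing section, the 3' UTR and coding sequence of 1 transcript per gene were taken from the basic set of GENCODE release 29. Words of 7 bases were scanned over 12329 tested protein-coding genes with a 3' UTR of at least 30 bases. Each word's presence was fitted to the log2 fold change, limited to ±3, together with splines of 3' UTR length, 3' UTR GC content, average log2 CPM, transcript GC content and transcript length. Words present in fewer than 30 genes were left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for these steps and the plots.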

Results

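RNA-seq profiles were obtained from HaCaT keratinocytes transfected with siRNAs against PAXBP1 or with control siRNA, 3 libraries each, to examine what PAXBP1 does in these cells. PAXBP1 encodes a nuclear protein named for its binding to PAX transcription factors and is a relative of the splicing-associated factor GCFC2. The control libraries held between 16355509 and 16833568 counts and the knockdown libraries between 16254032 and 20311280. Log2 CPM profiles correlated across genes with r between 0.990 and 0.992 within groups and between 0.956 and 0.960 between groups, where genes are not independent replicates. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 2.73 within groups, so no library was a copy of another. Mitochondrially encoded genes took 5.78% ± 0.31 of the counts in control and 6.15% ± 0.44 in knockdown libraries (SD, n = 3). The mitochondrial rRNA genes took 1% ± 0.06 and 1.34% ± 0.08 (SD, n = 3), with no overlap between the groups. Between 22507 and 22827 genes had reads in the control libraries and between 23909 and 24751 in the knockdown libraries.

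PAXBP1 (ENSG00000159086; hg38 chromosome 21, 32733899 to 32771858, minus strand) was lower in every knockdown library. Its level was 44.0, 47.1 and 45.8 CPM in the 3 control libraries and 22.9, 21.1 and 21.2 CPM in the 3 knockdown libraries. The means were 45.6 ± 1.5 and 21.7 ± 1.0 CPM (SD, n = 3), a 2.10-fold fall with a log2 fold change of -1.07 (SE 0.079, adjusted p = 3.66e-17 by edgeR's quasi-likelihood test). Its antisense gene PAXBP1-AS1 (chromosome 21, 32728115 to 32743122, plus strand) overlaps it, and without stated strand counting their shared reads cannot be told apart. PAXBP1-AS1 had a log2 fold change of 0.57 (adjusted p = 0.0681). That p was 0.0257 without knockdown replicate 3. It ranged from 0.0591 to 0.199 over another scaling and other tools, and was at most 0.292 with another library left out. The neighbouring gene SYNJ1, which encodes the phosphatase synaptojanin 1, fell by 0.35 on the log2 scale, and the paralog GCFC2 fell by 0.50. Of the splicing factors DHX15 and TFIP11, which act together in spliceosome disassembly, DHX15 fell by 0.13 (adjusted p = 0.0090) and TFIP11 had a log2 fold change of 0.02 (adjusted p = 0.852). The DHX15 call was lost without control replicate 3 (adjusted p = 0.0862) and with limma on log2(FPKM + 1) (0.0599), in a range from 0.00791 to 0.0862 over the alternatives.

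**Figure D1:**
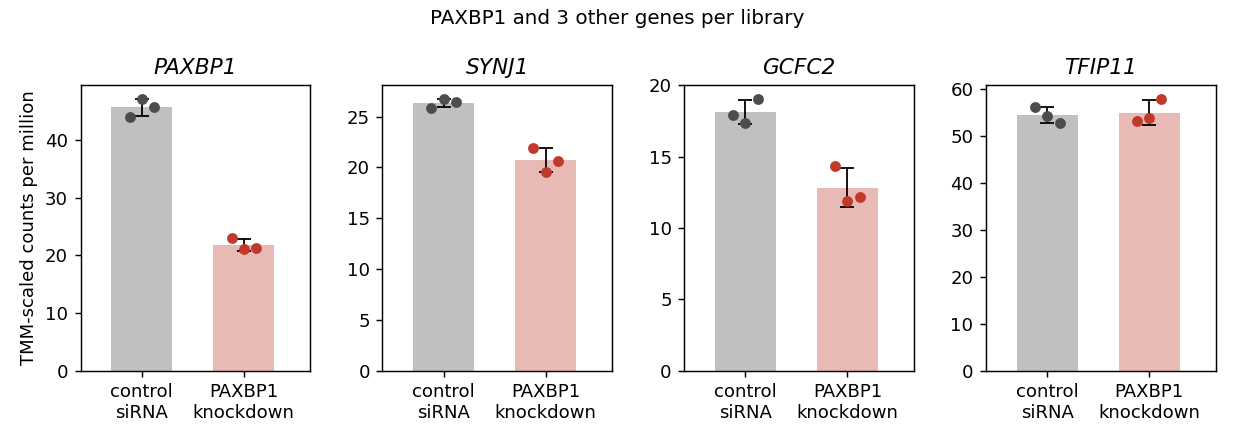
TMM-scaled CPM (vertical axes, from 0) of PAXBP1, SYNJ1, GCFC2 and TFIP11 in the control siRNA and PAXBP1 knockdown groups; points are libraries, bars are means and error bars are SD over 3 libraries. PAXBP1 lies at 21.7 CPM after knockdown against 45.6 in control, and TFIP11 overlaps between the groups.

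The next question was which other genes differed between knockdown and control cells. The abundant transcripts that fell farthest included S100A10, a calcium-binding-family partner of annexin A2, which went from 415.3 ± 14.3 to 54.9 ± 2.3 CPM (SD, n = 3). DEK, a chromatin-binding protein, went from 594 ± 15.4 to 91.6 ± 5.1 CPM. CCND1, the G1 cyclin D1, went from 1159 ± 16.1 to 343 ± 3.1 CPM, and the caveolar coat gene CAV1 from 2778 ± 51.4 to 946 ± 27.9 CPM. Among genes that rose, the nuclear receptor coactivator NCOA3 went from 252 ± 14.1 to 854 ± 16.6 CPM and PGM2L1 from 19.6 ± 1.2 to 122 ± 3.1 CPM. Involucrin (IVL), a precursor of the cornified envelope, rose from 6.98 ± 0.95 to 66.9 ± 3.9 CPM.

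In all, 4622 genes were higher and 4933 lower in knockdown at an adjusted p under 0.05 by edgeR, 62.5% of the 15277 tested. A change of at least 2-fold was reached by 1228 genes that were higher and 924 that were lower. With limma on log2(FPKM + 1), a scale that understates changes of low genes, these were 290 and 342. The groups did not overlap in 66.1% of the tested genes, where chance gives 10%. The median log2 fold change of the tested genes was -0.012. TMM scaling sets this centre near 0, so a shift shared by most genes would not be seen. With upper-quartile scaling the median was 0.0394, and 5061 genes were higher and 4457 lower. PAXBP1 itself was not among the most changed genes: 751 called genes had a lower log2 fold change than it did. Of 12558 protein-coding genes, 4055 were higher and 4535 lower, and of 2719 other genes 567 were higher and 398 lower.

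The 10 highest fold changes under the naming rule belonged to genes that were near the floor in control cells. They were CYP4F8 (log2 fold change 4.92), CLEC7A (4.77), ANK1 (4.70), ADAMTS5 (4.30), TNXB (4.23), TCN1 (4.20), SNCAIP (4.16), RBBP8NL (4.15), CLCA4 (4.11) and GFPT2 (3.82). CLEC7A, which encodes the innate receptor dectin-1, went from 0.379 ± 0.282 to 10.6 ± 1.3 CPM (SD, n = 3). In these 10 genes control libraries had between 0 and 11 reads each, so the size of the fold is imprecise. TNXB shares a near-identical stretch with a neighbouring pseudogene, which adds uncertainty to its count. The 10 lowest were MAMLD1 (-3.42), CD83 (-3.02), PPP1R14C (-2.93), S100A10 (-2.92), the mitochondrial import gene TIMM8B (-2.92), the haem synthesis enzyme gene CPOX (-2.75), DEK (-2.70), ZBTB8A (-2.63), STAMBPL1 (-2.63) and FJX1 (-2.62). S100A10 had the smallest p of all genes (adjusted p = 1.45e-43, SE 0.051), followed by DEK (adjusted p = 1.53e-43, SE 0.048). The next smallest p-values of lower genes belonged to CTNNAL1 (-2.20), the actin-binding transgelin 2 gene TAGLN2 (-1.87) and CCND1 (-1.76). Those of higher genes belonged to NCOA3 (1.76), PGM2L1 (2.63), FYB1 (1.99), MPZL2 (1.72) and the endothelial lipase gene LIPG (1.72). Of non-coding genes, NORAD, a long RNA that binds Pumilio proteins, rose from 356 ± 12.3 to 800 ± 14.3 CPM. AC079466.1 (2.22) and AC008957.3 (1.77) also rose, and SFTA1P (-2.44), AC245041.1 (-0.93) and THAP9-AS1 (-0.92) fell.

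**Figure D2:**
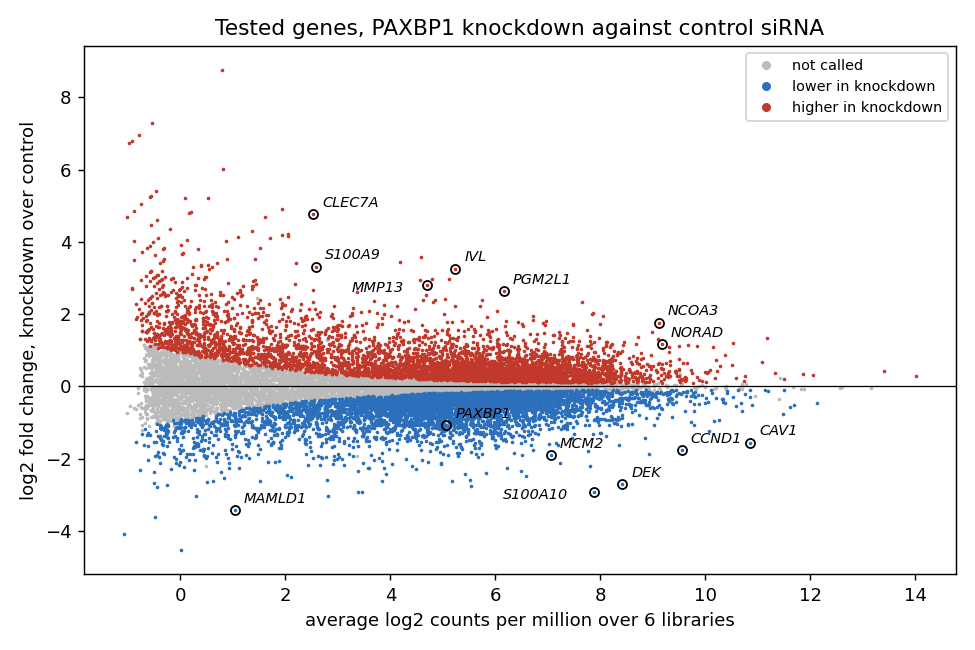
Log2 fold change of knockdown over control (vertical axis) against average log2 CPM over the 6 libraries (horizontal axis) for the 15277 tested genes; red points are the 4622 higher and blue points the 4933 lower genes at an adjusted p under 0.05, grey points were not called. Called genes lie on both sides of 0 over the whole range of levels, and PAXBP1 sits at -1.07.

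Genes of DNA replication fell almost throughout. Of 39 tested members of the list 38 fell and 1 rose, with a median log2 fold change of -1.16. Examples are the sliding clamp PCNA (-1.78, SE 0.048) and the replicative helicase subunits MCM2 (-1.90, SE 0.053), MCM5 (-1.76) and MCM6 (-1.62). The member that rose was CCNE1 (0.54), the cyclin that drives entry into S phase. Camera called the list down (adjusted p = 4.93e-37), and with an estimated correlation the adjusted p was 0.0276. The mitosis and G2/M list fell too, with 35 of 40 members lower and 1 higher and a median of -0.50. CKAP2L (-1.47), the mitotic kinase gene PLK1 (-1.15), the APC/C activator CDC20 (-0.92) and CDK1 (-0.88) were among them, and the phosphatase gene CDC25B (0.11) was the member that rose. Its adjusted p was 6.31e-11, and 0.165 with an estimated correlation, which does not pass.

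In the lists of ribosome biogenesis, ribosomal proteins and splicing regulators more members fell than rose, with smaller medians than in the replication list. In the ribosome biogenesis and MYC target list 24 of 35 members fell and 3 rose, with a median of -0.39. MRTO4 (-1.29), the box C/D snoRNP protein gene NOP56 (-1.01) and the polyamine enzyme gene ODC1 (-1.01) fell, while NOLC1 (0.84), MYC (0.22) and HSPD1 (0.19) rose. Of 45 cytosolic ribosomal protein genes 25 fell and 2 rose, with a median of -0.12. RPS15 (-1.62) and RPS3 (-0.97) fell by far more than that median, with RPL27 (-0.59) and RPL4 (-0.47) between, while RPL22 (0.25) and RPL12 (0.12) rose. Ribosomal protein genes have many processed pseudogenes, so their counts depend on how shared reads were treated. Of 25 SR and hnRNP splicing regulators 19 fell and 2 rose, with a median of -0.32. TRA2B (-0.85), SRSF7 (-0.64), SRSF6 (-0.54) and SRSF11 (-0.49) were among those that fell, and HNRNPM (0.20) and TRA2A (0.18) rose. Camera called all 3 lists down, with adjusted p of 5.15e-05, 0.00567 and 0.000895 in that order. With an estimated correlation the adjusted p were 0.103, 0.532 and 0.103, and no call held. The estimates were 0.0173, 0.232 and 0.00069. The last lies below the preset value, so correlation alone does not account for the loss in the splicing regulators.

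Core spliceosome genes and the partners of PAXBP1 moved both ways, and camera at the preset correlation called neither list. Of 34 core members 21 fell and 9 rose, with SF3A3 (-0.87), PRPF4 (-0.80) and SNRPD3 (-0.58) lower and SF3B2 (0.69) higher (median -0.23, camera adjusted p = 0.161). Of 16 PAXBP1 partner and splicing disassembly genes 11 fell and 3 rose, with ILF2 (-0.68), CWF19L1 (-0.55) and PAXIP1 (-0.48) lower and KMT2D (0.43), KMT2B (0.35) and RBBP5 (0.37), of histone methyltransferase complexes, higher (median -0.23, camera adjusted p = 0.262). Fry, which does not compare a list with other genes, called both down (adjusted p = 0.000752 for the core and 6.34e-05 for the partners). An alternative chosen after seeing the data left out genes that hold the words GCAGATC or CAGATCA, among them 10 of the 16 partner genes. Camera called the remaining 6 partner genes down at an adjusted p of 0.0334. The adjusted p of the partner list ranged from 6.34e-05 to 0.423 over the alternatives. Camera called the core list down with no low-count filter, at an adjusted p of 0.00583, in a range from 0.000752 to 0.323.

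Keratinocyte differentiation genes of the spinous layer and desmosome rose as a list. Of 19 tested members 15 rose and 2 fell, with a median of 0.37 (camera adjusted p = 7.4e-06, and 0.0791 with an estimated correlation, which does not pass). The desmosomal PERP (1.57), the receptor gene NOTCH1 (1.13), its ligand gene JAG1 (0.70) and the transcription factor gene KLF4 (1.11) rose, while KRT10 (-0.36), the suprabasal keratin, and DSG2 (-0.45) fell. In the cornified envelope list 9 of 21 members rose and 4 fell, and camera did not call it (adjusted p = 0.176), while fry called it up (0.000477), as did camera without genes that hold GCAGATC or CAGATCA (0.0382). IVL (3.26) rose and KLK10 (-0.91), the lipoxygenase-family gene ALOXE3 (-2.64), SPINK5 (-0.38) and the filaggrin gene FLG (-0.51) fell. CASP14, the caspase of terminal differentiation, had 0, 3 and 0 reads in the control and 44, 59 and 35 in the knockdown libraries (adjusted p = 4.93e-11).

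Histone, cholesterol, matrix, interferon and unfolded protein response lists were higher as well. Of 15 tested replication-dependent histone genes 11 rose and 1 fell, with a median of 0.85. HIST1H2BD (2.94), HIST2H2BE (1.59), HIST1H2AC (1.34) and HIST1H2BK (1.01) rose and HIST2H2AC (-1.66) fell; histone genes are near-identical copies, so the single-gene values are uncertain. In cholesterol biosynthesis 16 of 28 members rose and 5 fell (median 0.43), with HMGCS1 (1.13), MSMO1 (1.02) and INSIG1 (1.20) higher. STARD4 (-0.55), FDFT1 (-0.34), FDPS (-0.29), EBP (-0.29) and SREBF1 (-0.28) were lower. In the extracellular matrix and EMT list 22 of 37 rose and 9 fell (median 0.29). The collagenase gene MMP13 (2.80), TIMP3 (2.03) and ITGB6 (1.44) rose and TGFB2 (-1.68) fell. Of 41 interferon-stimulated genes 25 rose and 6 fell (median 0.38). OAS1 (1.46), OAS2 (1.60), OAS3 (0.86) and IFI27 (2.35) rose, while IFIT2 (-0.70), IFIT3 (-0.39), IFIT5 (-0.69), ISG15 (-0.40), OASL (-0.32) and GBP1 (-0.46) fell. In the ATF4 and unfolded protein response list 20 of 32 rose and 5 fell (median 0.29). The members that rose included the endoplasmic reticulum genes HERPUD1 (1.05), PDIA6 (0.70) and HSPA5 (0.58). Those that fell were ATF4 (-0.13) and genes of serine and folate metabolism, SHMT2 (-0.81), PSPH (-0.81), PSAT1 (-0.40) and MTHFD2 (-0.24). Camera adjusted p of the 5 lists, in the order histone, cholesterol, matrix, interferon and unfolded protein, were 5.15e-05, 1.25e-05, 0.00428, 5.15e-05 and 0.00567. With an estimated correlation the adjusted p were 0.103, 0.112, 0.112, 0.112 and 0.323, and no call held. The matrix list was also not called on log2(FPKM + 1), at an adjusted p of 0.0558, in a range from 6.34e-05 to 0.112 over the alternatives.

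**Figure D3:**
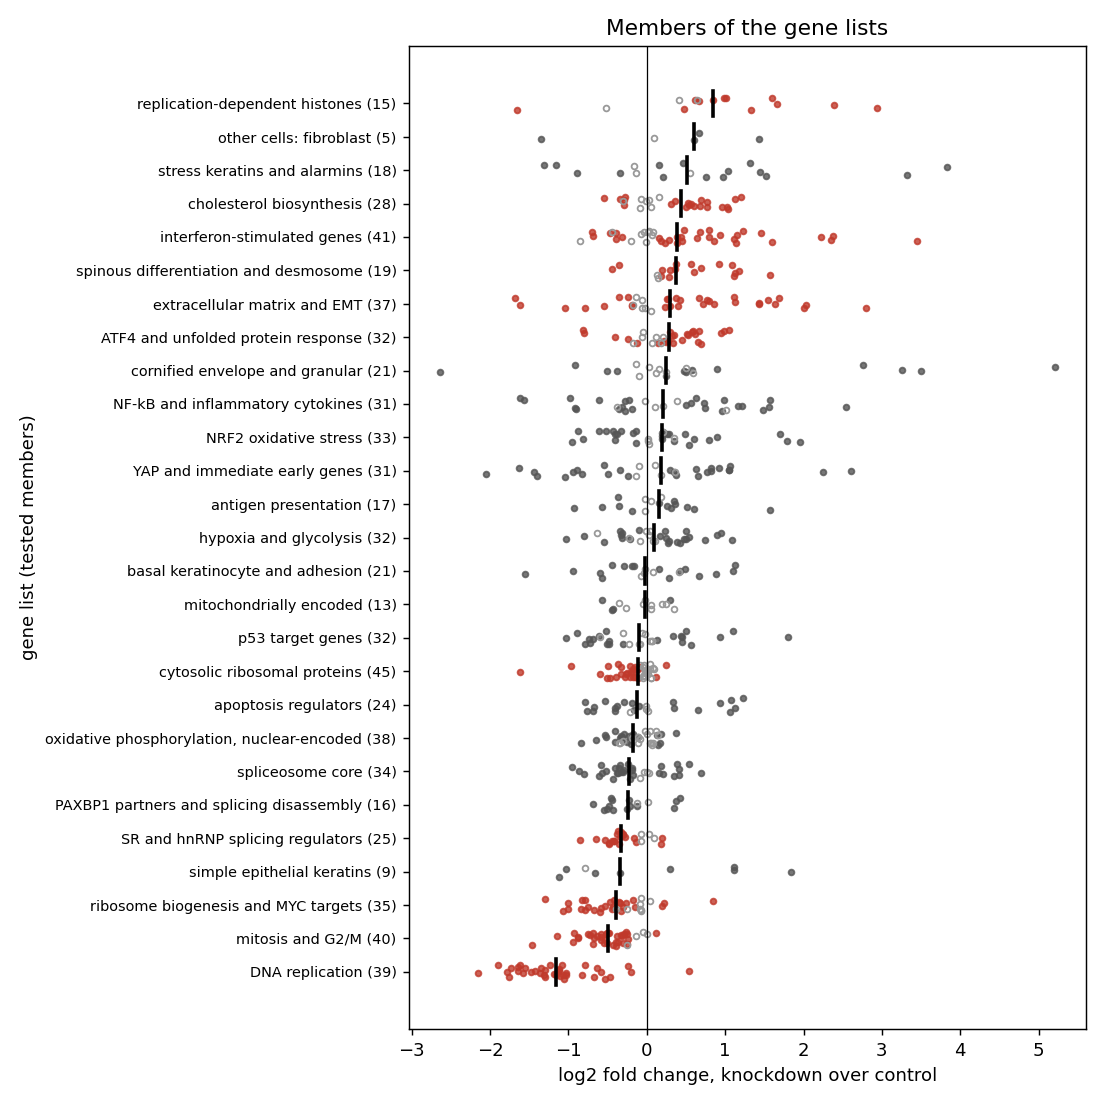
Log2 fold change of knockdown over control (horizontal axis) of each tested member of the gene lists with 5 or more tested members (vertical axis, number tested in brackets); filled points are called genes, open points are not called, black bars are medians, and filled points are red in the 11 lists that camera called at the preset correlation. DNA replication lies lowest with a median of -1.16 and replication-dependent histones highest with 0.85.

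The remaining lists had members changed in both directions, and camera at the preset correlation called none of them. The adjusted p given for each is camera's. Among 32 p53 target genes 10 rose and 12 fell, with BTG2 (1.80) and the cell cycle inhibitor gene CDKN1A (1.10) higher and BAX (-1.04) and the death receptor gene FAS (-0.89) lower (adjusted p = 0.90). Among 24 apoptosis regulators 8 rose and 12 fell, with BCL2L11 (1.08) and CASP10 (1.07) higher and CYCS (-0.79) lower (adjusted p = 0.792). Of 21 basal keratinocyte genes 8 rose, among them KRT15 (1.13), COL17A1 (1.10) and ITGA6 (0.88), and 8 fell, among them CAV1 (-1.55) (adjusted p = 0.467). Of 18 stress keratin and alarmin genes 11 rose and 4 fell, with S100A9 (3.32) and HBEGF (1.03) higher and KRT6A (-1.31), which has near-identical paralogs, SERPINB2 (-1.16), IL1RN (-0.89) and KRT17 (-0.35) lower (adjusted p = 0.42). In the keratin list of 9 genes, the simple epithelial keratins KRT18 (-1.03), KRT7 (-0.67) and KRT8 (-0.35) fell and KRT19 (0.30) rose. Its other members include KRT80 (-1.12), which fell, and the mucosal keratins KRT4 (1.11) and KRT13 (1.11) and the hair keratin KRT86 (1.83), which rose (adjusted p = 0.138). Of 31 NF-kB and cytokine genes 13 rose and 12 fell, with PTGS2 (2.54), CXCL1 (1.57) and CSF1 (0.96) higher and IL1B (-0.90) lower (adjusted p = 0.103). Of 31 YAP and immediate early genes 14 rose and 12 fell, with AXL (-1.63), FOSL1 (-1.44) and F3 (-0.95) lower and FOSL2 (0.92) higher (adjusted p = 0.792). Of these 7 lists fry called NF-kB up (0.000752), stress keratins up (0.00378) and the keratin list down (0.00177), and camera with no low-count filter also called the keratin list down (0.0106).

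Camera at the preset correlation also called none of the metabolic and antigen lists. Of 33 NRF2 oxidative stress genes 15 rose and 13 fell, with AKR1B10 (1.70) and SLC7A11 (0.79) higher and TXN (-0.88) and TALDO1 (-0.96) lower (adjusted p = 0.433). Of 32 hypoxia and glycolysis genes 15 rose and 9 fell, with KDM3A (0.89), ALDOA (1.09) and SLC2A1 (0.54) higher and ENO1 (-0.55) lower (adjusted p = 0.19). Of 38 nuclear-encoded oxidative phosphorylation genes 5 rose and 17 fell, with NDUFS1 (-0.84), ATP5F1A (-0.41), NDUFA4 (-0.52) and NDUFB10 (-0.65) lower and NDUFB5 (0.18), COX6C (0.17), SDHA (0.14) and SDHC (0.13) among those higher (adjusted p = 0.193). Of 13 mitochondrially encoded genes MT-CO1 (0.29) rose and MT-CO3 (-0.45), MT-ATP6 (-0.57) and MT-ND3 (-0.43) fell (adjusted p = 0.792). The MT-ND3 call was lost without control replicate 3, knockdown replicate 1 or knockdown replicate 3, at adjusted p of 0.0681, 0.0597 and 0.0548, in a range from 0.00242 to 0.0681 over the alternatives. Fry called NRF2 up (0.00847), hypoxia up (0.00682) and oxidative phosphorylation down (0.00547). Camera called oxidative phosphorylation down with no low-count filter (0.011) and NRF2 up without genes that hold the words GCAGATC or CAGATCA (0.0498). Of 17 antigen presentation genes 8 rose and 5 fell, with TAP1 (0.51), TAPBP (0.34) and HLA-B (0.31) higher and CD74 (-0.93), NLRC5 (-0.57), PSMB9 (-0.37), PSMB8 (-0.36) and HLA-E (-0.19) lower (adjusted p = 0.44).

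The median, the mean and the camera test differed in sign for the p53, apoptosis, basal keratinocyte, simple keratin and YAP lists. Adjusted over the list alone, 12 rather than 11 histone, 16 rather than 15 spinous, 12 rather than 11 stress, 15 rather than 13 NF-kB, 16 rather than 15 NRF2 and 15 rather than 14 YAP genes were higher. Adjusted over the list alone, 7 rather than 6 interferon, 5 rather than 4 simple keratin, 11 rather than 9 hypoxia and 2 rather than 3 mitochondrially encoded genes were lower, and the other counts were equal.

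Few markers of other cell types passed the count filter. Of 14 fibroblast markers 5 were tested: COL3A1 (1.43) and COL1A1 (0.66), which are also in the matrix list, rose to 8.59 ± 0.81 and 11 ± 0.79 CPM (SD, n = 3), TAGLN (0.60) rose, ACTA2 (-1.34) fell and S100A4 had a log2 fold change of 0.10 (list adjusted p = 0.436 by camera and 0.00139, up, by fry). The TAGLN call was lost without control replicate 3 (adjusted p = 0.151) or knockdown replicate 2 (0.0852), and the ACTA2 call without knockdown replicate 1 (0.069). With DESeq2 the adjusted p were 0.0795 for TAGLN, 0.0667 for ACTA2 and 0.057 for MLANA, of the melanocyte list. The other 3 lists had too few tested members for a test. Of the melanocyte markers MLANA (1.43) rose to 1.08 ± 0.35 CPM, MITF (-0.80) fell from 23.4 ± 1.8 to 13.4 ± 1.1 CPM, and PMEL had a log2 fold change of 0.03 (adjusted p = 0.925). Of the leukocyte markers ITGAM (1.52), HLA-DRA (1.57) and CD14 (1.16) rose, to 1.85 ± 0.27, 1.11 ± 0.52 and 1.72 ± 0.47 CPM. The HLA-DRA call was lost without knockdown replicate 1 (adjusted p = 0.0731). Of the endothelial markers PECAM1 (2.78) rose to 1.02 ± 0.31 CPM, and CDH5 (0.25) and VWF (0.55) were not called.

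Some named genes share short sequence words in their annotated 3' UTRs. The words came from a scan of these same data, given in the closing section. Of all searched genes 14.7% hold GCAGATC or CAGATCA in the 3' UTR. The genes listed here are therefore no test of enrichment. The 8-base word GCAGATCA occurs in S100A10, DEK, PPP1R14C, MRTO4, CYCS, NDUFS1 and KLK10, which fell, and in CASP10, which rose. Its first 7 bases occur without the last in CKAP2L and TGFB2, which fell, and in HBEGF and PECAM1, which rose. Its last 7 bases, CAGATCA, occur without the first in CD83, TIMM8B, FOSL1, TALDO1 and KRT6A, which fell, in ADAMTS5 and SLC2A1, which rose, and in CDH5, which was not called.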

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

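The alternative without genes holding the sequence words, and no other, was chosen after seeing the data. PAXBP1, which holds a word in its coding sequence and so has no value in that alternative, stayed lower in the others, with log2 fold changes from -1.10 to -0.86 over scalings, filters, tools and units and from -1.11 to -1.05 over the left-out libraries. Counts of higher and lower genes stayed within 1.5 times of 4622 and 4933 over the scalings, filters, tools and units, from 4230 to 5061 and from 4341 to 5089, and no gene called in both fits changed sign. With a library left out they ranged from 4315 to 4591 and from 4600 to 4820, and at 2-fold or more from 1228 to 1363 and from 934 to 998. Counts at 2-fold or more fell to 290 higher and 342 lower with limma on log2(FPKM + 1), since the added 1 shrinks the folds of low genes. Without genes holding the words, fewer genes were tested, and 2995 were higher, 3146 lower and 555 lower by 2-fold or more. In that alternative 8 lists were higher and 6 lower, where 6 and 5 were called with all genes. The added ones were PAXBP1 partners (down, adjusted p = 0.0334), cornified envelope (up, 0.0382) and NRF2 (up, 0.0498), and the cause was not tested. Of their tested members 10 of 16, 8 of 21 and 13 of 33, in that order, held a word and were left out. Camera with an estimated correlation called 0 lists up and 1 down, and fry, which does not compare a list with other genes, called 12 up and 9 down. With no low-count filter 8 lists were lower (the added ones were spliceosome core, simple keratins and oxidative phosphorylation), and the cause was not tested. No list call changed when a library was left out. Of 156 other named genes 3 lost their call in DESeq2 (ACTA2, TAGLN and MLANA), 1 with limma on log2(FPKM + 1) (DHX15), and 5 lost and 1 gained a call in some left-out library. No called result changed sign. Of lists without a call, p53, apoptosis, YAP and mitochondrially encoded changed direction in some alternatives. No paired analysis was possible because the groups share no number in the labels. Depth limits genes near the floor, where a few reads set the fold.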

Other observations

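The tests of Alu elements, of the replication list by sequence word and of RNA without a poly(A) tail were chosen after the results were seen, as were the gene families described first. Protein-coding genes were grouped by the letters (at least 3) before the first digit of their symbol, which gave 151 families of at least 10 tested genes, and camera at the preset correlation called 9 lower and 6 higher. With an estimated correlation 0 of the 151 families were called, the lowest adjusted p being 0.137 for MCM. In MCM 9 of 10 genes fell, with an adjusted p of 4.32e-15 by camera at the preset correlation. Most MCM genes are also in the DNA replication list, so this family is no separate measure of the power of the estimated setting. With 6 libraries its lack of calls decides little. The calls at the preset correlation may still include families whose members are correlated. Of 49 genes of the mitochondrial large ribosomal subunit (MRPL) 37 fell and 0 rose, with a median log2 fold change of -0.44 (adjusted p = 2.63e-05, and 0.292 with an estimated correlation), and MRPL41 (-1.51) and MRPL17 (-1.30) were the lowest. Of 29 genes of the small subunit (MRPS) 24 fell and 1, MRPS6 (0.31), rose (median -0.38, adjusted p = 0.00602, and 0.292 with an estimated correlation), and of 15 inner membrane import genes (TIMM) 13 fell and 0 rose (median -0.80, adjusted p = 0.000288, and 0.44 with an estimated correlation). Of 21 nucleoporin genes (NUP) 17 fell and 0 rose, with NUP210 (-1.70) and NUP54 (-1.62) lowest (adjusted p = 7.86e-05, and 0.70 with an estimated correlation). The 10 tested RNA exosome genes (EXOSC) all fell, with a median of -0.80 (adjusted p = 0.000378, and 0.292 with an estimated correlation).

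In the other direction, 13 of 17 histone lysine demethylase genes (KDM) rose and 0 fell, with a median of 0.36 (adjusted p = 2.63e-05, and 0.292 with an estimated correlation), led by KDM7A (2.13), KDM4B (1.30) and KDM5B (1.22). Of 13 Krüppel-like factor genes (KLF) 9 rose and 1 fell, with KLF7 (1.08), KLF5 (0.78) and KLF13 (0.76) higher and KLF11 (-0.71) lower, and of 19 semaphorin genes (SEMA) 12 rose and 3 fell (adjusted p = 0.00525 and 0.00478, and 0.292 for both with an estimated correlation). These directions were equal under DESeq2 size factors and upper-quartile scaling, and of the 6 higher families CYP (adjusted p = 0.0465) lost its call under both (0.0529 and 0.0688).

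A sequence word was more frequent among genes that fell. Among all 16384 words of 7 bases in 3' UTRs, GCAGATC had the lowest partial t on odd-numbered chromosomes (t = -9.60), and on even-numbered chromosomes the 443 genes with it lay lower than the others by a shift of -0.392 (95% interval -0.463 to -0.322), in a test set before the result was seen. Over all chromosomes GCAGATC (t = -14.66) and CAGATCA (t = -12.83) stood apart from the next word, GATCACT (t = -6.23), which overlaps both. Together GCAGATC and CAGATCA spell GCAGATCA, with shifts of -0.437 for the 8 bases, -0.350 and -0.212 for either 7 alone and -0.049 for the 6 they share. Alu elements, some of which hold the word, were marked by an exact match to a short Alu word, so diverged copies could be missed. Genes with the word and no Alu word shifted by -0.405, which argues against the marked Alu copies as the source. Each shift was fitted at equal GC content and transcript length, which over all genes explained 2.98% of the variance of the log2 fold change. This grading is consistent with an siRNA whose seed pairs with the word, and PAXBP1 holds GCAGATCA once, in the coding part of its exon 10 (hg38 chromosome 21, 32750985 to 32750992, minus strand), as do 7.6% of 1912 coding sequences of like length, but the siRNA sequences needed to tell are not given in the sources used here. Either 7-base word occurs in the 3' UTR of 26.5% of the searched genes that fell by 2-fold or more, 11.3% of those that rose as much and 14.7% of all searched genes, and what loss of PAXBP1 itself does stays open.

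The word with the highest partial t on the odd-numbered chromosomes, TTGTACA, gave a shift of 0.020 on the even-numbered ones (95% interval -0.032 to 0.072). Over all chromosomes the highest partial t belonged to CCCGGGG (t = 5.12), with a shift of 0.146 in 690 genes (95% interval 0.090 to 0.202). Genes with GCAGATC in the coding sequence alone were shifted by -0.216 (95% interval -0.254 to -0.178). Genes with an Alu word in the 3' UTR and neither of GCAGATC and CAGATCA were shifted by -0.131 (95% interval -0.175 to -0.087).

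Seed pairing with GCAGATC or CAGATCA in the members themselves was also set against the fall of the DNA replication list. The 20 members with neither word in the 3' UTR or coding sequence had a median log2 fold change of -1.063 (95% bootstrap interval -1.148 to -0.728), and 19 of them were below 0. This argues against pairing with these words as the whole source, and other seed words were not tested. The interval resamples genes measured in the same 6 libraries, which are not independent replicates. The 19 members that hold a word had a median of -1.34. MCM2, MCM5 and MCM6 are among these 19, with a word in the coding sequence. Removing GC content and transcript length moved the median of the list from -1.162 to -1.194. An indirect route, through genes such as the cell cycle regulators that fell, and the loss of PAXBP1 itself are not separated by this design.

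Replication-dependent histone genes rose while the replication genes fell, although their mRNAs are known to accumulate with S phase. One candidate explanation is that the knockdown libraries hold more RNA without a poly(A) tail. The 19 other tested RNAs of that kind had a median log2 fold change of 0.111 (95% bootstrap interval -0.111 to 0.391) against 0.850 for the histone list. Of the 19, 3 were called, 2 snoRNA genes and 1 snRNA gene, all higher in knockdown. The interval lies below the histone median, but these RNAs were near the floor (the highest, SNORD17, at 4.11 CPM in knockdown), so the comparison cannot decide. More of such RNA therefore cannot be told apart from a rise of polyadenylated histone transcripts, which some histone genes are known to make in differentiating cells.

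The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 9555 genes and the highest of the other splits called 0.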
